A study of Rattus norvegicus with 8 samples.

How the data were processed

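The series holds 8 Affymetrix rat genome U34 arrays of the A set of primary pulmonary artery smooth muscle cells grown from explants of adult Sprague-Dawley rat arteries stripped of endothelium and adventitia, per the labels' protocols. Cells were left untreated or exposed to S-nitrosoglutathione (GSNO), a nitric oxide donor, for 1, 2 or 4 h, with 2 arrays per group numbered 1 and 2. The sources disagree on the concentration: the series design gives 100 μmol/L and the treatment protocol of the samples gives 100 mmol/L. Neither was taken as the fact here. The series design speaks of 2 independent preparations of cells without saying that the array number is the preparation. Where the arrays of a group came from 1 preparation, the p-values would measure only the spread between arrays.

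Total RNA was extracted, converted to biotin-labelled cRNA and hybridised, and the authors analysed the scans with the array maker's version 5.0 software, per the series design. The deposited values are intensity values, 1 signal per probe set on a linear scale. The trimmed mean of signal, leaving out 2% at each end, lay between 495.4 and 498.5 on the 8 arrays, which is the mark of scaling by that software. The largest deviation from their mean was 0.318%, so the signals were used as deposited. The values held no detection calls, so a filter on such calls was not possible. The table holds 8799 probe sets, of which 59 are control features of the array and were kept out of the tests.

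An offset of 21.1 signal units was added before taking log2. This is the median over the arrays of each array's 20th percentile. It understates the fold changes of weak probe sets. A probe set was kept when its signal reached the array's 40th percentile on at least 2 of the 8 arrays, which left 5877 of 8740. No pair among the 28 pairs of arrays held identical values. Genes were named from GEO's platform annotation, with symbols checked through the gene ID: 7018 probe sets had 1 symbol, 308 had several and 1473 had none here. The ID of 6994 of the single-symbol probe sets was found in the RefSeq gene table, and 0 symbols changed. The kept probe sets with 1 symbol numbered 4841 and covered 3474 genes. No genome was used here, so no coordinates are given.

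Tests used limma 3.58.1 in R 4.3.3, with lmFit on the log2 values, all 4 groups in a single fit with 4 residual degrees of freedom, and eBayes with a trend of variance on expression. All p-values are two-sided and adjusted by the Benjamini-Hochberg method over the 5877 probe sets, with a threshold of 0.05. Each exposure time was compared with control, the times were compared with each other, and limma's moderated F test covered the 3 times against control. Errors of log2 fold changes are standard errors (SE) of this fit. Signals are given as mean ± SD with n = 2. The precision is limited by the number of arrays.

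Whether the array numbers pair the arrays was checked before calls were compared. The deviations from the group means of arrays with the same number correlated between 0.387 and 0.569 for all 6 pairs of groups, above the minimum of 0.1 set in advance. The first principal component, with 32.4% of the variance, parted the numbers. The experiment records show the same split: the 4 arrays numbered 1 and the 4 numbered 2 were scanned on 2 different days, here called runs. They also had different fluidics settings and chip lots, 3 lots in all. A fit with the array number as a replicate block is therefore given beside the counts of each comparison, and for single genes and lists where stated. The block leaves each fold change as it is, because every group holds both numbers, and changes only its error. The records also name 3 experiments. The control and 2 h arrays numbered 1 share 1 of them, the 1 h and 4 h arrays numbered 1 another, and all arrays numbered 2 the last, and this record was tried as a block too. The 1 h array numbered 1 was the only array of its chip lot. Among the arrays numbered 1, an effect of the lot can therefore not be told apart from 1 h of GSNO.

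Before the data were examined, 25 gene lists were fixed: immediate early genes; NRF2 and antioxidant genes; heat shock genes; the unfolded protein and integrated stress response; p53 targets; cAMP and cGMP CREB targets; nitric oxide and cGMP signalling components; smooth muscle contractile genes; inflammatory and NF-kB genes; TGF-beta and BMP pathway genes; cell cycle genes; extracellular matrix and remodelling genes; cholesterol synthesis and SREBP2 targets; glycolysis and hypoxia genes; circadian clock genes; vasoactive receptors and ligands; growth factors and receptors; potassium and calcium channels; ribosomal proteins; mitochondrial respiration genes; and markers of endothelium, of fibroblasts and adventitia, of macrophages and leukocytes, of lung epithelium and of cardiac and skeletal muscle. Lists with at least 5 kept genes were tested with limma's camera at an inter-gene correlation of 0.01, using for each gene the kept probe set with the highest mean, and adjusted over 72 tests of 24 lists. The p53 list had 4 kept genes and was not tested. Camera with an estimated correlation and limma's fry, which asks whether a list's genes move on balance in 1 direction, were alternatives.

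The genes named in the text follow a rule fixed at the same time. For each time against control it takes the 12 largest rises and 12 largest falls in log2 fold change among probe sets with 1 symbol past the threshold. Where fewer than 5 passed in a direction, places up to 5 went to the largest moderated statistics. It also takes up to 4 members per list, the 5 smallest p-values between times, and 15 genes chosen in advance, of which Prkg1 was not named on the array. Genes named outside the rule are said to be so.

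The alternatives were no offset, an offset at the 40th percentile, no filter, a filter at the 60th percentile, quantile normalization, scaling to a common median, the array number or the recorded experiment as a block, no variance trend, only the 2 groups compared, and each array left out. A description without a test counted probe sets with both GSNO arrays at least 2-fold above or below both control arrays. For overlaps, unchanged groups sharing the controls were simulated 100 times. The fits were tested on simulated data with 200 changed probe sets among 5877. For 4 h against control, the fit recovered 22.7% of the 4-fold changes and 0 of 67 of the 2-fold changes, with 0 false calls. With the array number as a replicate block it recovered 66.7% and 23.9%, with 1 false call. For 1 h against control the fit recovered 42.4% of the 4-fold changes, and 84.8% with the block. For 2 h against control these shares were 33.3% and 71.2%. The simulated data were made with the array-number effect and the errors of the replicate-block fit. The higher recovery with the block was thus built in and is no evidence for the block. In 20 simulations of 25 genes, camera called the list shifted by 0.5 in 20 and an unshifted list in 0, before adjustment. Unlike the simulated probe sets, these lists held no array-number effect, but they too had the errors of the replicate-block fit. Camera was run on them without the block, so the 20 may overstate how often it finds such a shift in the real data. The simulated genes varied independently of each other, so these simulations could not show false calls that come from correlation between genes. Figures were drawn with matplotlib.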

Results

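RNA from cultured rat pulmonary artery smooth muscle cells was measured on 8 arrays: untreated cells and cells exposed to the nitric oxide donor GSNO for 1, 2 and 4 h, with 2 arrays in each of the 4 groups. The design asks how transcript levels move over the first hours of exposure to a nitric oxide donor. The untreated cells form 1 group with no stated time. Changes with time in culture can therefore not be told apart from effects of GSNO. The median signal per array ran from 100.0 to 141.2, and the 99th percentile from 9213 to 15901. The 3' to 5' signal ratios were 0.926 to 1.11 for beta-actin and 0.934 to 1.08 for GAPDH, so neither control transcript showed loss of the 5' end on any array. The arrays numbered 1 and 2 came from separate runs, and the CreX hybridisation spike read 11786 to 13184 in the first and 3305 to 4100 in the second. The 2 h array numbered 1 had the highest 20th percentile of signal, 38.1 against 16.4 to 28.5 on the others.

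At 1 h, the largest rises included the transcription factors Nr4a3, Klf4, Nr4a1 and Nr4a2. Signal of Nr4a3, an orphan nuclear receptor, went from 79.4 ± 71.7 (SD, n = 2) in control to 3348 ± 391, a log2 fold change of 5.28 ± 0.46 (SE; limma adjusted p = 0.00399). It was 4.59 between the arrays numbered 1 and 5.96 between those numbered 2. Its relatives Nr4a1 and Nr4a2 rose by 4.63 and 4.24, and the zinc finger factor Klf4 rose by 5.11 ± 0.34 (adjusted p = 0.0017). Crem, a modulator of cAMP-responsive transcription, rose by 3.21 and Pde4b, a phosphodiesterase that breaks down cAMP, by 2.43. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, rose by 2.76 (adjusted p = 0.00576).

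In all, 29 probe sets rose and 2 fell at 1 h, covering 16 genes that rose and 1 that fell, the zinc finger factor Klf6 (log2 fold change -2.60, adjusted p = 0.0486). Other rises were Errfi1 (3.60), the transcription factors Cebpb (2.48), Junb (2.42) and Klf10 (2.38), Cyp1b1 (1.89), Tuba4a (3.38), the stress cytokine Gdf15 (2.35) and the hexokinase gene Hk2 (4.37). Control signals of Tuba4a, Gdf15 and Hk2 lay below the 40th percentile on both control arrays. The other Hk2 probe set gave 1.06 at 1 h (adjusted p = 1.00) and did not pass at any time. For Nr4a3, Errfi1, Junb, Cyp1b1, Klf10 and Pde4b, too, some probe sets passed at 1 h and others did not: the other Nr4a3 probe set gave 1.59 (adjusted p = 0.462) and 1 of Errfi1 gave 1.44 (adjusted p = 1.00). Below the threshold in this fit were Edn1, the endothelin-1 precursor (-2.94, adjusted p = 0.0665), Myc (-3.72, adjusted p = 0.131), Apoc3 (-1.70, adjusted p = 0.136) and Dcn (-2.30, adjusted p = 0.13).

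Of 11 kept CREB targets, 6 rose and 0 fell at 1 h, among them Nr4a1, Crem and Pde4b, and the list shifted upward (median 2.43, camera adjusted p = 7.3e-37; adjusted p = 0.0604 with an estimated correlation). Its median was 2.33 between the arrays numbered 1 and 2.24 between those numbered 2. Adjusted over the list alone, 9 members rose, and 7 of the 11 are also members of other lists. Of 28 immediate early genes, 6 rose and 1 fell, with 10 and 2 adjusted over the list alone (median 0.25, camera adjusted p = 3.52e-12; adjusted p = 0.119 with an estimated correlation). This list shares 6 kept genes with other lists. Among 19 genes of the unfolded protein and integrated stress response, Cebpb was the 1 gene that rose, with 3 adjusted over the list alone (camera adjusted p = 5.86e-05; adjusted p = 0.119 with an estimated correlation). The inflammatory list shifted upward with 0 of 18 genes called and 3 that rose adjusted over the list alone (camera adjusted p = 6.9e-06; adjusted p = 0.119 with an estimated correlation). Fibroblast and adventitial markers shifted downward with 0 of 6 genes called and 1 that fell adjusted over the list alone (median -0.25, camera adjusted p = 0.022; adjusted p = 0.445 with an estimated correlation and 0.0532 with the replicate block). In the fibroblast list, Dcn is the probe set named above, while the other kept Dcn probe set gave 0.53 at 1 h and was not called. Within runs the medians of the immediate early, stress response, inflammatory and fibroblast lists were 0.24, 0.13, 0.55 and -0.14 for arrays numbered 1, and 0.33, 0.19, 0.22 and -0.31 for arrays numbered 2.

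With the array number as a replicate block, 67 probe sets rose and 12 fell at 1 h, including all 31 called without it, of which 26 were called with the recorded experiment as the block, and Hmox1 (log2 fold change 2.00), Edn1 and Myc passed (adjusted p = 0.00517, 0.00296 and 0.0162). The count of 31 fell to 5 and 8 without the 1 h arrays numbered 1 and 2, and to 20 and 15 without the control arrays numbered 1 and 2.

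At 2 h, Hmox1 and Nqo1, which had not passed at 1 h, were past the threshold beside Gclc. Gclc rose by 4.08 ± 0.28 (SE; adjusted p = 8.45e-04), Hmox1, the inducible haem oxygenase, by 3.86 ± 0.41 (adjusted p = 0.00507) and Nqo1, a quinone reductase, by 3.20 ± 0.34 (adjusted p = 0.00507). Hmox1 signal was 552 ± 138 (SD, n = 2) in control and 8542 ± 3617 at 2 h, and its fold change was 4.55 and 3.16 between the arrays numbered 1 and 2. Edn1 fell by 3.81 (1461 ± 572 in control, 80.6 ± 8.05 at 2 h, adjusted p = 0.0132), and the growth factor gene Bmp4 fell by 2.70 (adjusted p = 0.0327).

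Klf4 (5.37), Nr4a3 (5.40), Crem (4.13) and Pde4b (3.18) remained above control at 2 h, and the cytokine gene Il6 rose by 3.85 from a control signal below the 40th percentile. The other Nr4a3 probe set gave 0.99 (adjusted p = 0.828), and 1 of Pde4b gave 0.94 (adjusted p = 0.77). Cyp1b1 rose by 3.17 and Fgfr1 by 1.31. Also lower were Lbh (-2.97), Cnksr3 (-2.83), Klf6 (-2.71), the transcription factors Egr1 (-2.24) and Ets1 (-2.19), Prx (-1.72) and the antiproliferative gene Btg1 (-1.46). For Egr1, the probe set with the highest mean gave -1.65 (adjusted p = 0.0774), and the others gave -1.78 (adjusted p = 0.0928) and -0.43, neither of them called. The other kept Ets1 probe set gave -1.60 (adjusted p = 0.577). In all, 46 probe sets rose and 11 fell, covering 24 and 9 genes.

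Of 25 NRF2 and antioxidant genes, 3 rose at 2 h, Gclc, Hmox1 and Nqo1, with 3 adjusted over the list alone (median 0.21, camera adjusted p = 1.69e-06; adjusted p = 0.119 with an estimated correlation). CREB targets still had 6 of 11 genes higher, with 7 higher and 1 lower adjusted over the list alone (median 2.21, camera adjusted p = 3.76e-16; adjusted p = 0.0995 with an estimated correlation). Of the immediate early genes 5 rose and 1 fell, with 9 and 3 adjusted over the list alone (camera adjusted p = 1.02e-06; adjusted p = 0.197 with an estimated correlation). The stress response list had 1 gene that rose, with 4 adjusted over the list alone (camera adjusted p = 1.08e-05; adjusted p = 0.113 with an estimated correlation), and the inflammatory list had 1, Il6, with 3 adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.218 with an estimated correlation). Circadian clock genes shifted upward with 0 of 10 genes called, also adjusted over the list alone (median 0.50, camera adjusted p = 0.0412; adjusted p = 0.484 with an estimated correlation). Within runs the medians of the NRF2, CREB, immediate early, stress response, inflammatory and circadian lists were 0.36, 2.15, 0.13, 0.18, 0.32 and 0.63 for arrays numbered 1, and 0.16, 2.28, 0.72, 0.43, 0.16 and 0.47 for arrays numbered 2.

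With the array number as a replicate block, 129 probe sets rose and 57 fell at 2 h, and all 57 called without it were among them; with the recorded experiment as the block 107 rose and 45 fell, and with only the 2 groups compared 32 rose and 5 fell. The count of 57 fell to 19 and 29 without the 2 h arrays numbered 1 and 2, and to 23 and 31 without the control arrays numbered 1 and 2.

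At 4 h, the transcript of a subunit of the nitric oxide receptor was among the largest falls. Gucy1b1, the beta subunit of soluble guanylate cyclase, had a signal of 2761 ± 691 (SD, n = 2) in control and 284 ± 44.4 at 4 h, a log2 fold change of -3.17 ± 0.30 (SE; adjusted p = 0.00229). It was -3.28 between the arrays numbered 1 and -3.07 between those numbered 2. The alpha subunit Gucy1a1 gave -3.19 ± 0.77, which did not pass (adjusted p = 0.101), and passed with the replicate block (adjusted p = 1.33e-04). Hmox1 rose by 4.64, Nqo1 by 4.59 and Gclc by 4.46 (adjusted p = 0.0019, 8.42e-04 and 7.69e-04). The other Hmox1 probe set gave 4.82 at 2 h and 4.71 at 4 h. Cyp1b1, a cytochrome P450, rose by 4.09 ± 0.28, from 571 ± 24.2 to 10176 ± 2012.

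In all, 56 probe sets rose and 34 fell at 4 h, covering 34 and 24 genes. Klf4 (4.96), Crem (4.30), Il6 (4.36), Nr4a3 (3.70), Klf10 (2.95), Pde4b (2.76), Errfi1 (2.21), Cebpb (2.19), Gdf15 (2.12) and Hk2 (4.55) rose. For Nr4a3 the other probe set gave -0.94 (adjusted p = 0.487), and 1 of Pde4b gave 0.07 (adjusted p = 0.973). Fgfr1 rose by 2.19 and 2.87 in 2 probe sets, while another gave -0.71 (adjusted p = 0.679). Cd55, a complement regulator (3.14, from a control signal below the 40th percentile), Sod2, the mitochondrial superoxide dismutase (1.83), and the lactate transporter Slc16a3 (1.63) passed at 4 h alone. The other Cd55 probe set gave 1.32 (adjusted p = 0.295), and the other Sorbs2 probe sets -1.17 and -1.90 (adjusted p = 0.263 and 0.15). None of the other 5 Bdnf probe sets passed, with the lowest adjusted p at 0.0537, and 1 of Errfi1 gave 0.78 (adjusted p = 0.638). Nr4a1 stood at 2.30, which did not pass (adjusted p = 0.0739). Besides Gucy1b1, the falls included Lbh (-4.01), Edn1 (-3.22), Cnksr3 (-3.07), Tnfrsf11b, which encodes osteoprotegerin (-2.92), Pln, which encodes phospholamban (-2.89), Egr1 (-2.68), Nexn (-2.60), Sorbs2 (-2.59), Bdnf (-2.46), Gpr176 (-2.02), P2ry6 (adjusted p = 0.0135), Btg1 (-1.43) and the sterol synthesis gene Msmo1 (-1.34). Dusp6 (-2.68) and Dcn (-2.42) fell to signals below the 40th percentile on both 4 h arrays. Of the other Egr1 probe sets, 1 gave -1.27 at 4 h (adjusted p = 0.277) and the rest were called as lower.

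**Figure D1:**
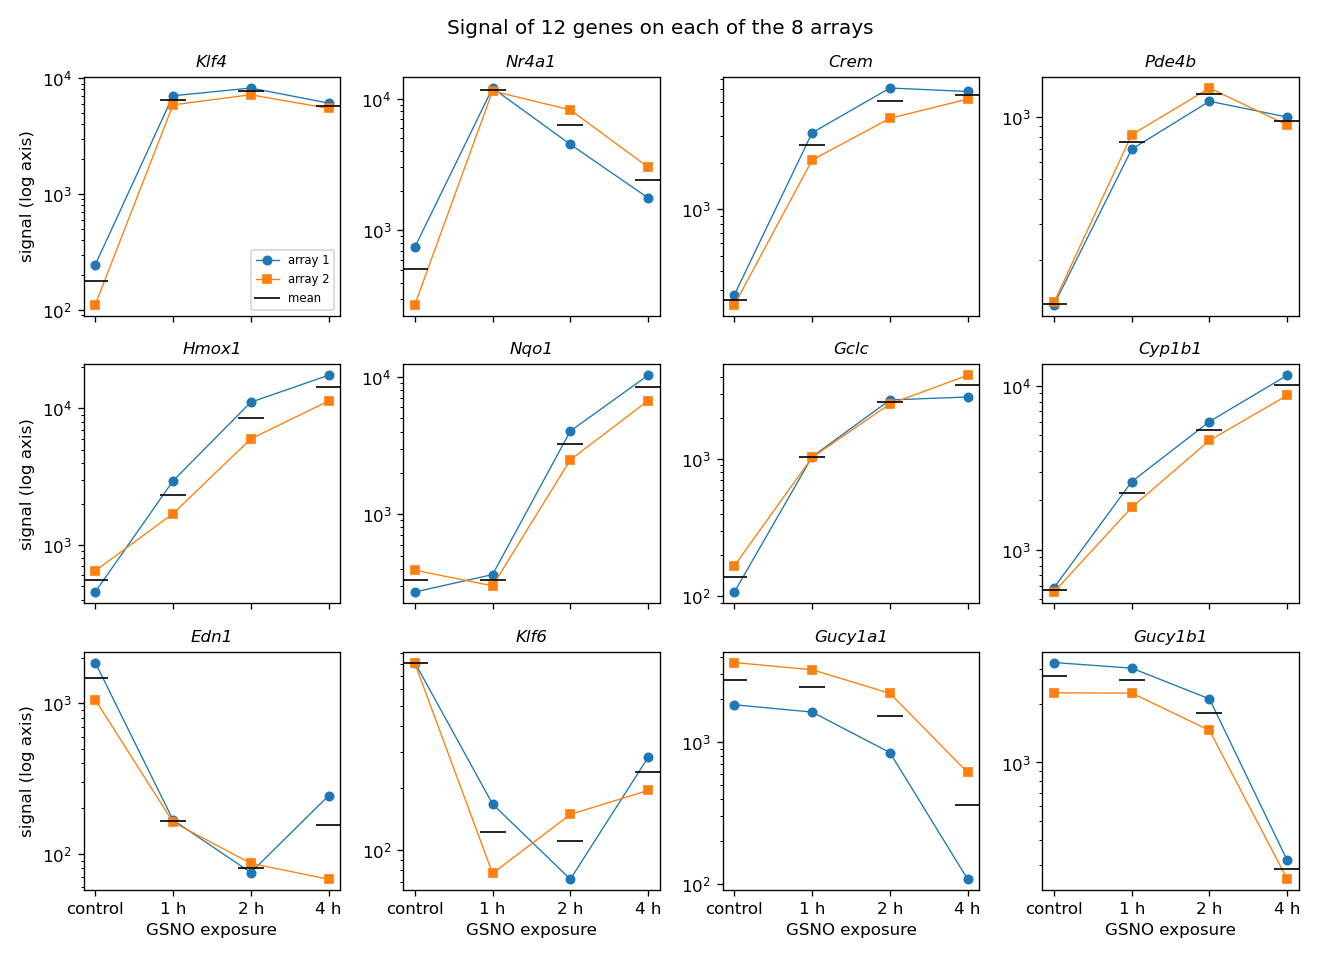
Signal of 12 genes on each array, on a log axis, against exposure to GSNO (control, 1, 2 and 4 h); circles are the arrays numbered 1, squares those numbered 2, and bars the group means (n = 2). Klf4 and Nr4a1 stood highest at 1 to 2 h, Hmox1, Nqo1, Gclc and Cyp1b1 had their highest means at 4 h, and Gucy1b1 was at 284 at 4 h against 2761 in control.

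Of the 25 NRF2 and antioxidant genes, 5 rose and 0 fell at 4 h, with 11 adjusted over the list alone and 16 with the replicate block (median 0.97, camera adjusted p = 1.07e-15; adjusted p = 0.0899 with an estimated correlation). The median was 0.83 and 0.76 between the arrays numbered 1 and 2. CREB targets had 4 of 11 genes higher, with 6 higher and 1 lower adjusted over the list alone (median 1.22, camera adjusted p = 2.98e-08; adjusted p = 0.119 with an estimated correlation). Immediate early genes had 3 higher and 1 lower, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.00978; adjusted p = 0.484 with an estimated correlation). Their median was -0.02 between the arrays numbered 1 and 0.43 between those numbered 2. The stress response list had 1 gene that rose, also adjusted over the list alone (camera adjusted p = 0.0046; adjusted p = 0.159 with an estimated correlation). Glycolysis and hypoxia genes shifted upward with Slc16a3 higher and Edn1 lower among 23, and 2 higher and 1 lower adjusted over the list alone (median 0.32, camera adjusted p = 0.00157; adjusted p = 0.445 with an estimated correlation). Within runs the medians of the CREB, stress response and glycolysis lists were 0.87, 0.19 and 0.18 for arrays numbered 1, and 1.56, 0.39 and 0.39 for arrays numbered 2. The 21 nitric oxide and cGMP signalling components held 2 falls, Gucy1b1 and Pln, and 5 falls adjusted over the list alone, and the list did not pass (median -0.24, camera adjusted p = 0.103), but passed with the replicate block (adjusted p = 0.04; adjusted p = 0.688 with the block and an estimated correlation).

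The median log2 fold change of all kept probe sets at 4 h was -0.16, and scaling to a common median moved it to 0.04, so small changes at 4 h depend on the scaling. The split of 56 higher and 34 lower became 83 and 21 with that scaling. Gucy1b1 stayed at -2.97 and the 16 called list shifts kept their direction and their call under it and under quantile normalization. With the array number as a replicate block, 250 probe sets rose and 216 fell, including all 90 called without it, and with the recorded experiment as the block 92 rose and 73 fell, including 80 of the 90. The count of 90 fell to 32 and 45 without the control arrays numbered 1 and 2, and to 41 without the 4 h array numbered 2.

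**Figure D2:**
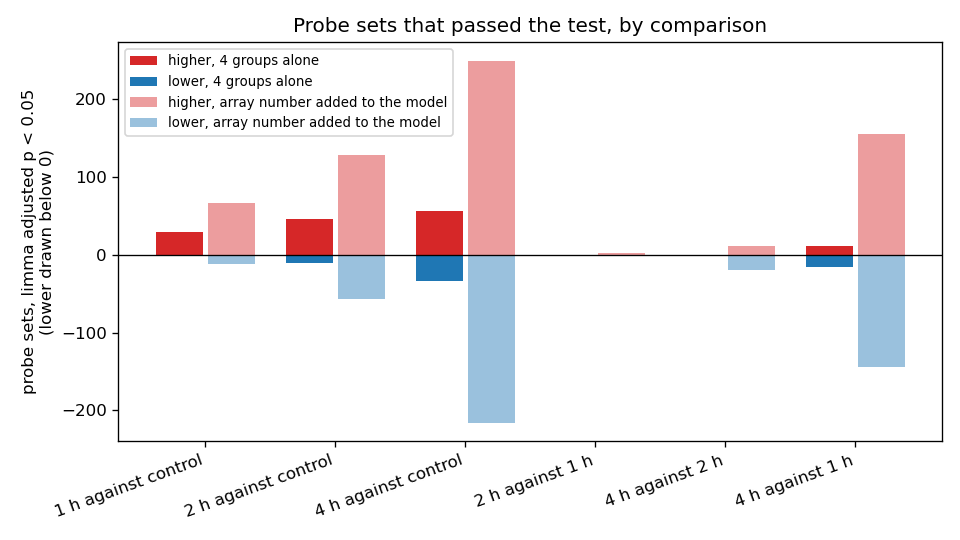
Number of probe sets past a limma adjusted p of 0.05 in each comparison, drawn upward from 0 when higher and downward when lower. Dark bars are the fit of the 4 groups alone (56 higher and 34 lower at 4 h) and pale bars the fit with the array number added (250 and 216).

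Comparing exposure times directly, Nqo1 was 4.57 ± 0.34 (SE) higher on the log2 scale at 4 h than at 1 h (adjusted p = 0.00435) and Gucy1b1 was lower (-3.12 ± 0.30, adjusted p = 0.012). Cd55 (2.71), Hmox1 (2.64), Fgfr1 (2.64), Cyp1b1 (2.20) and Sod2 (1.83) were also higher at 4 h. Nr4a2 (-3.02), Ptgs2, an inducible prostaglandin synthase (-3.06), Tnfrsf11b (-2.81), Sorbs2 (-2.80), Cnksr3 (-2.45) and Bdnf (-2.31) were lower. In all, 12 probe sets were higher and 16 lower at 4 h than at 1 h. With the replicate block these were 156 and 144, and with the recorded experiment as the block 101 and 100. Scaling to a common median gave 18 and 6. The count of 28 fell to 2 and 0 without the 1 h arrays numbered 1 and 2, to 2 and 4 without the 4 h arrays, to 3 without either control array and to 17 without the 2 h array numbered 1.

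Between neighbouring times, limma called 0 probe sets for 2 h against 1 h, where 164 had an unadjusted p under 0.05, and 0 for 4 h against 2 h, where 330 did. About 294 would have such a p by chance, and with the replicate block 431 and 752 did. Without the block, 1 h against control also gave only 177, although 31 probe sets were called there, and with the block it gave 337. The fit without the block counts the difference between the array numbers as error, although every group holds both numbers. Its errors are therefore too large for many probe sets, and a missing call in it is weak evidence of no change. With the replicate block 2 were higher at 2 h than at 1 h, and 12 were higher and 20 lower at 4 h than at 2 h. Over the 3 times together, limma's F test called 67 probe sets, and 349 with the replicate block. Of the 52 that stood furthest above control, 14 did so at 1 h, 14 at 2 h and 24 at 4 h, and of the 15 that stood furthest below, 0, 2 and 13 did. The count of 67 fell to 23 and 24 without the control arrays numbered 1 and 2, and to 33 and 38 without the 1 h arrays.

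The responses at the 3 times shared many probe sets. Of 29 higher at 1 h and 46 at 2 h, 28 were shared, where independent lists would share 0.227. The 2 h and 4 h lists shared 37 higher probe sets (0.438) and 7 lower ones (0.0636), and the 1 h and 4 h lists shared 20 higher and 1 lower. Across probe sets, log2 fold changes correlated at 0.724 for 1 h and 2 h, 0.541 for 1 h and 4 h and 0.712 for 2 h and 4 h. Genes are not independent replicates, and unchanged groups set against the same controls gave 0.501, 0.499 and 0.5. The covariances were 0.193, 0.173 and 0.281, and the simulated one 0.126, 0.125 and 0.125, leaving 0.0677, 0.0477 and 0.156. A replicate block in the fit and the simulation left 0.128, 0.108 and 0.216, with simulated covariances of 0.0655, 0.0654 and 0.0655. Errors in the simulation without the block include the difference between the array numbers, drawn separately for each array. In the data same-numbered arrays share that difference and it leaves the fold changes as they are. The simulated covariances without the block are therefore too large for these data. The controls could not be split, so part of the shared calls may come from the shared control arrays.

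By size alone, both GSNO arrays lay at least 2-fold above both control arrays for 65 probe sets at 1 h, 100 at 2 h and 130 at 4 h, and at least 2-fold below for 12, 43 and 93. Splitting the same 4 arrays by array number gave 199, 197 and 127 such probe sets in both directions together, against 77, 143 and 223 for the split by treatment. The crossed split gave 3, 3 and 8. By chance, 33.3% of probe sets have groups that do not overlap, whatever the gap, if the arrays are exchangeable. The counts above need a 2-fold gap, and the split by array number shows that the arrays were not exchangeable. That share is therefore no measure of how many to expect here.

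Smooth muscle contractile genes did not pass at any time, and 0 of 13 changed, with 1 fall at 4 h with the replicate block; at 4 h their median was -0.26 (camera adjusted p = 0.739). Acta2, smooth muscle actin, had log2 fold changes of -0.20, -0.37 and -0.26 at 1, 2 and 4 h, and Pde5a, which breaks down cGMP, of -0.28, -0.09 and -0.20, none past the threshold. Fos gave 0.74 and Dusp1 1.13 at 1 h, and Jun, Atf3 and Cdkn1a gave 0.71, -0.57 and 1.48 at 4 h, with none past the threshold. Other Fos probe sets gave 2.22 and 1.53 at 1 h (adjusted p = 0.204 and 0.218). Another Cdkn1a probe set rose by 1.83 at 4 h (adjusted p = 0.0429). The 4 kept p53 targets held 0 calls at each time, and 1 rise at 2 h and at 4 h with the replicate block.

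Of the other lists, none passed at 4 h. Their camera adjusted p at 4 h was 0.986 for heat shock genes, 0.71 for TGF-beta and BMP genes, 0.942 for cell cycle genes, 0.942 for extracellular matrix genes and 0.739 for cholesterol synthesis genes. It was 0.26 for vasoactive receptors and ligands, 0.942 for growth factors and receptors, 0.17 for potassium and calcium channels, 0.66 for ribosomal proteins and 0.26 for mitochondrial respiration genes. The TGF-beta and BMP list held 1 fall at 2 h, Bmp4, and 0 calls at 4 h. At 4 h it had 5 falls and 1 rise adjusted over the list alone, 6 falls and 1 rise with the replicate block, and a shift downward by fry (adjusted p = 0.0474). Fry does not set a list against the other genes, and the median of all kept probe sets at 4 h was -0.16. It was not run under the other scalings, so part of this shift may follow that median. Tgfb3 of the TGF-beta and BMP list fell at 4 h in another probe set (-1.89, adjusted p = 0.0273). Vasoactive receptors and ligands held 2 falls at 4 h, Edn1 and P2ry6, and growth factors and receptors held 2 rises, Fgfr1 and Gdf15. In these lists, 0 calls were made at any time for heat shock, cell cycle, channel, ribosomal and mitochondrial genes. With the replicate block at 4 h there were 1 fall among heat shock genes, 2 rises and 3 falls among cell cycle genes, 1 fall among channel genes, 1 rise among mitochondrial genes and 0 calls among ribosomal genes. In 18 of the 72 list tests, none of them called, the median, the mean and the direction of the test differed in sign.

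Markers of other cell types did not pass at 4 h, with camera adjusted p of 0.739 for endothelium, 0.603 for fibroblasts and adventitia, 0.739 for macrophages and leukocytes, 0.526 for lung epithelium and 0.346 for cardiac and skeletal muscle. The endothelial marker Thbd read 673 ± 54.1 (SD, n = 2) in control with a log2 fold change of 1.18 at 4 h (adjusted p = 0.196) and of 2.59 in its other probe set (adjusted p = 0.107), while Edn1 of the same list fell. The endothelial list had 1 rise and 1 fall at 4 h adjusted over the list alone, and the same counts with the replicate block. S100a4, a fibroblast marker, read 7523 ± 163 in control (0.03 at 4 h, adjusted p = 0.981). Of the 6 kept fibroblast markers, 3 are also members of other lists, as are 3 of the 6 endothelial ones.

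**Figure D3:**
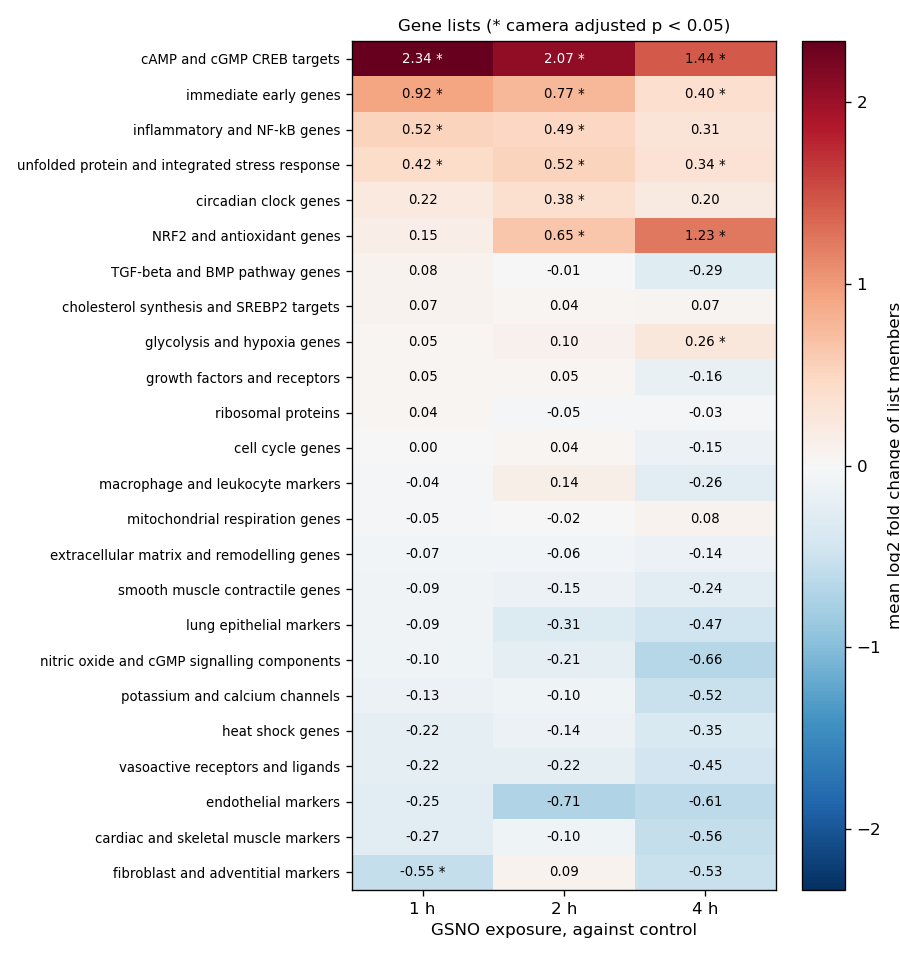
Mean log2 fold change against control of the kept members of 24 gene lists at 1, 2 and 4 h of GSNO, with the colour scale in log2 units centred on 0; stars mark a camera adjusted p under 0.05, none of which held with an estimated correlation. CREB targets went from 2.34 at 1 h to 1.44 at 4 h, and NRF2 and antioxidant genes from 0.15 to 1.23.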

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

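Of the tests in this part, those on the share of smooth muscle RNA, on cross-hybridisation and on the recorded experiment were chosen only after the results were seen, except the simulation of the loss of precision.

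Signal differed between 4 h and 1 h of GSNO, by limma's test of the difference, for 13 named genes in 14 probe sets. Without untreated cells for each time, a change with time in culture cannot be told apart from one with GSNO. On the log2 scale, Nqo1 (4.57), Cd55 (2.71), Hmox1 (2.64), Fgfr1 (2.64 and 1.91 in 2 probe sets), Cyp1b1 (2.20) and Sod2 (1.83) were higher at 4 h than at 1 h. Gucy1b1 (-3.12), Ptgs2 (-3.06), Nr4a2 (-3.02), Tnfrsf11b (-2.81), Sorbs2 (-2.80), Cnksr3 (-2.45) and Bdnf (-2.31) were lower.

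Outside the main measurement, the middle hexokinase control feature of the array stood at 376 against 151 in control at 4 h in the first run and at 1527 against 459 in the second, at least 2.31-fold higher in both. The 5' and 3' features of that transcript were not above this 2-fold level in both runs.

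Several technical explanations of the fall of Gucy1b1 at 4 h were examined. Gucy1a1 was put through the same scalings, offsets, filters and recorded-experiment block. Over the other scalings, offsets and filters the highest Gucy1b1 log2 fold change at 4 h was -2.97, so its size depended little on these settings. A filter cannot change a fold change, and array medians of 100.0 to 141.2 left the scalings little room. The processing was therefore not put to a test that it could fail. Between the arrays numbered 2, which share a recorded experiment, the Gucy1b1 log2 fold change was -3.07. With that record as a block it was -3.09 (95% interval -3.57 to -2.62), and both values argue against that record. The contractile list had a median of -0.26 with a lower quartile of -0.46, so a lower share of smooth muscle RNA does not account for a fall of this size. A change in transcription or transcript stability under GSNO stays open as a hypothesis, untested here. Gucy1a1 lay between -3.33 and -2.92 under the scalings, offsets and filters, where its adjusted p was 0.0772 to 0.113. It passed only with a block, and with the recorded experiment as the block it was -2.96 (95% interval -3.82 to -2.09).

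For Cyp1b1 and Nqo1, the lowest log2 fold change at 4 h among their 6 kept probe sets was 3.02, which argues against cross-hybridisation of a single probe set, though probe sets of a gene can share sequence. Both genes are known targets of the aryl hydrocarbon receptor, so its activation was a hypothesis. Cyp1a1, its most inducible target, gave -0.39, but its probe set lay below the 40th percentile on all 8 arrays, so whether that receptor was active cannot be told apart from a gene that is silent in these cells. Nqo1 is also an NRF2 target, and that list is described with the other lists.

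With the recorded experiment as a block, 165 probe sets were called at 4 h, against 466 with the array number as the block. In simulated data without an effect of the recorded experiment, the mean counts were 184.7 and 778.65. This ratio was 0.237, below the 0.354 observed, so the loss of precision alone could give such a fall. The simulation overstated the calls with the array number as the block, so its support is weak. The spread between runs of the contrast that parts 1 h and 4 h from control and 2 h was 0.978 times the larger of the others, which argues against a broad shift with the record. Shifts of single genes stay open.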

How the results depend on the processing

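No named gene called against control changed sign there under any alternative. Calls of named genes between times were not put through the alternatives. Leaving out arrays with the array number in the model was chosen after the data were seen. The cause of the differences below was not tested, except that leaving out an array or comparing 2 groups also lowers the residual degrees of freedom. Gucy1b1, Hmox1, Nqo1, Gclc, Crem, Klf4, Cyp1b1, Il6 and Tnfrsf11b passed at 4 h under all 18 alternatives, with Gucy1b1 between -3.43 and -2.92 and a highest adjusted p of 0.0228. Prx at 2 h and Klf6 at 1 h lost their call under 15 of 18.

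With the array number as a replicate block the counts were 79 at 1 h, 186 at 2 h, 466 at 4 h, 349 at any time, 2 for 2 h against 1 h, 32 for 4 h against 2 h and 300 for 4 h against 1 h. Shared higher calls became 62 for 1 h and 2 h, 53 for 1 h and 4 h and 104 for 2 h and 4 h, and shared lower calls 9, 8 and 44. With the recorded experiment as a block, counts became 152 at 2 h, 165 at 4 h, 192 at any time, 1 for 4 h against 2 h and 201 for 4 h against 1 h. Without a variance trend 4 h against 1 h gave 4, and with only the 2 groups compared 0, with 37 at 2 h. Quantile normalization gave 1 for 2 h against 1 h. The 1.5-fold rule gave 154, 275 and 474 separated probe sets. Offsets, filters, median scaling and the rule of 2-fold in both same-numbered pairs kept each total count against control, between times and of separated probe sets within 1.5 times, though median scaling moved the lower calls from 34 to 21 at 4 h and from 16 to 6 for 4 h against 1 h. Shared calls were recomputed with the replicate block alone.

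Camera with an estimated correlation called 0 lists at each time, and fry 1, 1 and 3; using all probe sets of each gene gave 9 lists at 4 h. Leaving out single arrays gave 5 to 27 probe sets at 1 h, 19 to 52 at 2 h, 32 to 87 at 4 h, 23 to 53 at any time, 0 for 2 h against 1 h, 0 to 1 for 4 h against 2 h and 0 to 23 for 4 h against 1 h. For lists it gave 3 (without the 1 h array numbered 1) to 9 (without the control array numbered 2) at 1 h, 5 to 9 at 2 h and 4 to 7 at 4 h. With the array number in the model these ranges were 48 to 94, 81 to 225, 184 to 480 and 214 to 360 against control, and 0 to 12, 1 to 102 and 93 to 294 between times. A group left with 1 array was assumed to vary like the others. Detection calls could not be used, so weak signals are limited by the 40th percentile alone.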

Other observations

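The tests of gene lists between 1 h and 4 h in this part were chosen only after the values against control were seen, and the genes named here lie outside the rule for named genes and were chosen after their values were seen. Further rises at 4 h included the monocarboxylate transporter Slc16a1 (log2 fold change 2.69 ± 0.36 SE, limma adjusted p = 0.0106), the branched-chain aminotransferase Bcat1 (1.68 ± 0.23, adjusted p = 0.0122), Gchfr, which encodes a regulator of tetrahydrobiopterin synthesis (2.26 ± 0.30, adjusted p = 0.0102) and Taldo1 of the pentose phosphate pathway (1.35 ± 0.25, adjusted p = 0.0432). Falls at 4 h included Pdlim1 (-1.39 ± 0.23, adjusted p = 0.027), Ptk2, which encodes focal adhesion kinase (-1.64 ± 0.28, adjusted p = 0.0308), Marcks (-1.52 ± 0.29, adjusted p = 0.0456) and Myo1c (-1.33 ± 0.25, adjusted p = 0.0463). Ptk2 signal was 2219 ± 65.4 (SD, n = 2) in control and 713 ± 203 at 4 h. Id3, an inhibitor of helix-loop-helix factors, was lower at 4 h than at 1 h (-2.12 ± 0.28, adjusted p = 0.0334).

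The NRF2 and antioxidant list was higher at 4 h than at 1 h (median difference 1.04, camera adjusted p = 1.05e-16; adjusted p = 0.151 with an estimated correlation), which restates its values against control and is no separate test of a late rise. That immediate early genes return towards control by 4 h was not borne out at the threshold (camera adjusted p = 0.0974), while CREB targets were lower at 4 h than at 1 h (median difference -0.81, camera adjusted p = 0.00674; adjusted p = 0.742 with an estimated correlation). Glycolysis and hypoxia genes were higher (camera adjusted p = 0.0202; adjusted p = 0.742 with an estimated correlation). These, too, restate the values against control.

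A single Dcn probe set alternated between arrays: from a signal of 185 ± 20.8 (SD, n = 2) in control its log2 fold changes were -2.30 at 1 h, 0.37 at 2 h and -2.42 at 4 h, with the first 2 not past the threshold, and the call at 4 h was lost under 11 of 17 alternatives. Among the arrays numbered 1 the split of 1 h and 4 h from control and 2 h is also that of the recorded experiments. Between the arrays numbered 2, which share 1 record, the log2 fold changes were -2.23, 0.83 and -2.48. The other kept Dcn probe set gave 0.53 at 1 h, 0.17 at 2 h and -0.35 at 4 h (adjusted p = 0.914 at 4 h).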
